A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

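Ribosome footprints were measured in 4 libraries of Saccharomyces cerevisiae, 2 from an L7-TAP strain (tagged Rpl7b) and 2 from a Not4-FTP strain (tagged Not4). Footprints were obtained by immunoprecipitation of ribosomes and RNase I treatment, in an order left open here, and were sequenced. Per the submitters' processing notes, CASAVA 1.8, UMI-tools 1.0.1, Bowtie2 2.2.5 and TopHat2 2.1.1 were used with the sacCer3 genome; the role of each tool, the read length filter and the assignment of footprints to sites were not stated. The deposited values are pause scores, a ratio that the authors made per library: the footprints at a codon position over the mean of its gene. Each position is listed with the codons in the E, P and A sites, positions without footprints included. The position number was taken as that of the P-site codon.

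Scores of a gene are whole multiples of a step, the worth of 1 footprint, so footprints were recovered as score over step; 100% of the scores were whole within 0.01. Recovery was checked on 300 simulated genes, and all 300 came back. The depth was 15266332 and 14096312 footprints in L7 and 32772211 and 31318545 in Not4, with a median of 1.90, 1.86, 4.06 and 3.91 footprints per codon. Footprints were summed over genes, so a read shared by near-identical copies may count more than once. Reads had molecular identifiers, per the tool named, but whether each footprint is a distinct molecule was not stated. Replicates differed by more than counting error, with chi-square per degree of freedom of 7.07 in L7 and 5.97 in Not4, so the spread between libraries was estimated from the libraries and not from counts. Genes entered with at least 0.5 footprints per codon in all 4 libraries (3277 of 5227 listed genes).

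Before the data were examined, the comparisons, 24 gene lists, 16 codon lists, the alternatives and the rule for named items were fixed. The design had foreseen counts, and because the deposited unit is a ratio, recovered footprints were analysed with limma on the log2 scale in place of the count models. Codon scores were the mean pause score of each sense codon in a site over the mean of all sense codons, as log2. Gene values were log2 of footprints per 1000000 (FPM) plus 0.5, scaled with the trimmed mean of M-values (trim 30% and 5%), which was rewritten in numpy. Windows were the first 20 codons, codons 21 to 50, the last 20 and the rest of genes of at least 120 codons. Positions were tested as log2 of the score plus 0.5. All used limma 3.58.1 in R 4.3.3 with group as the only term, a trend for genes and positions, and Benjamini-Hochberg adjustment with a threshold of 0.05. Lists were tested with camera at its preset correlation, again with an estimated correlation, and with fry. With an estimated correlation camera rests on the residual degrees of freedom of the 4 libraries alone. These are so few that calls can be lost whatever the correlation, so a lost call does not show that members are correlated. Single values had exact two-sided permutation tests, whose smallest p with 2 against 2 libraries is 0.333. Correlations across codons used 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 served for the rest, and gene coordinates came from the R64 reference table.

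The gene lists were Ccr4-Not, tagged genes, ribosomal proteins, mitochondrial ribosomal proteins, mitochondrially encoded genes, respiratory chain, tricarboxylic acid cycle, glycolysis, translation factors, tRNA synthetases, ribosome biogenesis, proteasome, SAGA and TFIID, RNA polymerase II, chaperones, secretory endoplasmic reticulum, secreted cell wall, plasma membrane transporters, ergosterol, amino acid synthesis, histones, mRNA decay, cell cycle, and stress and trehalose. Named genes were the 10 with the largest increase and the 10 with the largest decrease among those past the threshold, with both Not4 libraries on one side of both L7 libraries and a mean of at least 100 footprints, all measured members of the Ccr4-Not and tagged lists, and up to 3 called members of each called list with the smallest adjusted p. Named codons were up to 8 with the largest increase and 8 with the largest decrease per site, and the 6 arginine codons. Named positions were the 5 largest increases and 5 largest decreases. Families of near-identical genes were those sharing at least 50% of their 10-codon windows.

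The pipeline was tested on simulated data. With 100 genes changed by 1 and 100 by 0.5 on the log2 scale, all 200 were called, with 10 false calls among the other genes. Of 6 codons changed in the A site 6 were called, with 0 false calls there and 0 in the P site, and the 1 changed gene list was called, with 0 false calls. The test of single positions called 741 of 1000 changed positions and 50008 unchanged ones. With at least 10 footprints in every library it called 978 of 1000 and 13 unchanged ones, so that limit was added after the data were seen. The simulated positions varied by counting error only, less than the real replicates, so these counts do not give the error rate in the data. The alternatives covered coverage filters, capped scores, weights, the ends of genes, the site assignment, depth, scaling, pseudocounts, thresholds, the replicate number as a block, leaving out each library, and the set tests. Added after the data were seen were 1 gene per family, the 50% of genes least changed, the median of ratios, and the limit of 10 footprints. Codon optimality by tRNA gene number was left out because the reference table gives no anticodons.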

Results

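The series holds 4 ribosome profiling libraries of budding yeast from 2 strains that share their auxotrophic markers, with 2 replicates each. In the L7-TAP strain a large subunit protein, Rpl7b, carried a tandem affinity tag, so that the pulldown took ribosomes in general. In the Not4-FTP strain the tag was on Not4 (gene MOT2), the ubiquitin ligase of the Ccr4-Not complex. That complex shortens poly(A) tails and starts mRNA decay, and the pulldown was meant to take ribosomes bound by it. A pulldown made before RNase I treatment could also bring other ribosomes on the same mRNA, and the order is left open here. Footprints were made with RNase I and each score refers to 1 codon position. The recovered footprints numbered 15266332 and 14096312 in the L7 libraries and 32772211 and 31318545 in the Not4 libraries. Of these, 34.2% and 34.4% in Not4 and 1.06% in each L7 library lay in 2 retrotransposon families. Their near-identical copies seem to count the same reads, so part of the greater Not4 depth may be repeated counting. The L7 libraries listed 3432 and 3308 genes and the Not4 libraries 5211 and 5188. The comparisons below use the 3277 genes that had at least 0.5 footprints per codon in all 4 libraries, with 1377394 codon positions. Gene totals of replicates correlated across these genes with r = 0.998 for L7 and r = 0.999 for Not4, against r = 0.689 between the first library of each group. The labels do not say that the replicates came from separate cultures, so each p-value measures the spread between samples only, and tag, strain and pulldown cannot be separated in this design.

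The first question, given by the series title, was whether ribosomes held by Ccr4-Not carry other codons than ribosomes in general. In the A site, where the next aminoacyl-tRNA binds, Not4 ribosomes were rich in the rare arginine codon CGG, whose relative pause score rose from 0.667 ± 0.0337 (SD, n = 2) to 2.90 ± 0.0312. The leucine codon CTG rose from 0.845 ± 0.0165 to 2.82 ± 0.0392, and the arginine codon CGA, which yeast reads through an inosine-adenosine pair and which slows translation, rose from 0.890 to 2.31. All 6 serine codons rose, led by TCT (log2 change 1.19) and TCC (1.04). All 4 proline codons fell, and CCT, the most strongly changed of them, went from 1.62 ± 0.00817 to 0.825 ± 0.00681.

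Of the 61 sense codons in the A site, 25 rose, 30 fell and 6 did not pass the test. The log2 change was 2.12 (SE 0.04) for CGG with adjusted p = 1.36e-07, 1.74 (SE 0.02) for CTG with adjusted p = 1.10e-07, and 1.38 (SE 0.06) for CGA with adjusted p = 6.60e-06. The other serine codons among the 8 largest increases were AGT (0.90), TCG (0.88) and TCA (0.69). Among the remaining arginine codons CGT (0.43) and CGC (0.39) rose and AGA, the main arginine codon of yeast, fell by 0.20. The AGG codon rose by 0.09 with adjusted p = 0.0421, but its change was 0.05 without Not4-FTP replicate 2. It was −0.02 (adjusted p = 0.664) without the first and last 20 codons of each gene. With 1 gene per family it was −0.04 (adjusted p = 0.262), and with the 50% of genes least changed −0.09 (adjusted p = 0.0305). The positions averaged include 1 site in 32 copies of a retrotransposon gene (Ty1) that share reads. There, with AGG in the A site, the median score was 10.97 in L7 and 47.6 in Not4. The rise is therefore not one of AGG codons in general. CGT stood at −0.22 when genes were weighted by their footprints. Besides CCT (−0.97, adjusted p = 1.92e-07), the decreases were led by the proline codons CCC (−0.82), CCA (−0.69) and CCG (−0.52), the cysteine codon TGC (−0.51), the tyrosine codon TAT (−0.47), the alanine codon GCC (−0.39) and the phenylalanine codon TTT (−0.38). CCG still had a score of 2.18 in the Not4 libraries, against 3.13 in the L7 libraries. Among 16 codon lists fixed in advance, serine (adjusted p = 0.0115), leucine, with 5 of 6 codons raised (adjusted p = 0.0384), and the 4 CGN arginine codons (adjusted p = 0.0384) were called up and proline (adjusted p = 0.0384) down. None of these held with an estimated correlation: the adjusted p was 0.431 with an estimated correlation for serine, leucine and CGN arginine, and 0.432 for proline, and at unadjusted p under 0.05 camera with that correlation called 0 lists. Leucine lost its call although its estimated correlation was negative (−0.114), since that version of camera has few residual degrees of freedom. At the preset correlation the other 12 lists, wobble pairs among them, had adjusted p from 0.0945 to 0.448. Adjusted over the list alone, each of the 16 lists had as many called codons as over all 61.

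In the P site, which holds the tRNA with the growing chain, CGA stood out: its score rose from 0.586 ± 0.0526 to 1.92 ± 0.0475 (SD, n = 2). The leucine codons CTT, CTG and CTA rose with it, CTT from 0.947 to 1.93, as did the serine codons TCG and AGT and the glutamine codon CAG. All 4 glycine codons fell, led by GGT, the main glycine codon of yeast, from 1.40 ± 0.00869 to 0.863 ± 0.0103, and so did both asparagine codons, AAT and AAC.

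In the P site 28 codons rose, 30 fell and 3 did not pass. The log2 change was 1.71 (SE 0.06, adjusted p = 1.15e-06) for CGA, 1.03 for CTT, 0.97 for TCG, 0.91 for CTG, 0.89 for AGT, 0.86 for CAG and for CGG, and 0.85 for CTA. The arginine codons AGG (0.68), AGA (0.45) and CGC (0.26) rose and CGT fell by 0.40, and weighted by footprints CGC was at 0.05 (adjusted p = 0.127). The largest decreases were those of GGT (−0.70, adjusted p = 6.62e-07), AAT (−0.65), GGC (−0.64), GGG (−0.58), GGA (−0.57), AAC (−0.47), the tyrosine codon TAT (−0.44) and the valine codon GTT (−0.43). None of the 16 lists passed with camera at the P site: adjusted p ran from 0.0685 for serine, with 6 of 6 codons raised, to 0.971. At unadjusted p under 0.05, 5 lists passed there, and fry called 14.

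In the E site, which a tRNA leaves, differences were smaller. As in the P site, CGA had the largest increase, from 0.973 ± 0.0571 to 1.797 ± 0.0508 (SD, n = 2). All 4 proline codons, lower in the A site of Not4 ribosomes, rose in the E site, CCC from 0.926 to 1.40, but CCC and CCA did not pass when genes were weighted by their footprints. The leucine codon CTT and the arginine codons CGG and CGC also rose, while AAT, GGT and GGA fell.

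In the E site 20 codons rose, 20 fell and 21 did not pass, and without Not4-FTP replicate 1 only 12 fell. The log2 changes were 0.89 for CGA (adjusted p = 1.88e-04), 0.60 for CCC, 0.53 for CCG, 0.50 for CTT, 0.44 for CCA and for CGG, 0.43 for CGC, 0.40 for CCT and 0.25 for AGA. They were −0.27 for AAT (adjusted p = 1.86e-04), −0.25 for GGT and for GGA, −0.20 for the alanine codon GCG, −0.19 for CAG and for GCC, −0.18 for the histidine codon CAT and −0.17 for AAC. Weighted by footprints, CCC (0.05, adjusted p = 0.124), CCA (0.02, adjusted p = 0.5996) and AAT (−0.03, adjusted p = 0.476) lost their calls and CAT turned to 0.32 (adjusted p = 1.32e-16). AAC lost its call without either Not4 library (adjusted p = 0.0703 and 0.0913) and CAG without Not4-FTP replicate 1 (adjusted p = 0.0569). CGT (−0.01) and AGG (0.04) did not pass. AGG was called up weighted by footprints (1.13, adjusted p = 2.82e-63), with 1 gene per family (0.17, adjusted p = 0.00620) and with the 50% of genes least changed (0.18, adjusted p = 0.00138). The weighted values lean on the retrotransposon families in Not4 and far less in L7, so they do not compare the same mix of genes. The proline list was called up (adjusted p = 0.0171), which was lost with an estimated correlation (adjusted p = 0.678 with an estimated correlation). The other 15 lists had adjusted p from 0.148 to 0.802. Measured at every offset within 12 codons of the A site, the SD of the codon differences was 0.563 at the A site and 0.502 at the P site, 0.224 at the E site and 0.239 at its highest elsewhere, 3 codons downstream of the A site. The plot of codon differences by place in the footprint shows both peaks above the replicate differences.

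**Figure D1:**
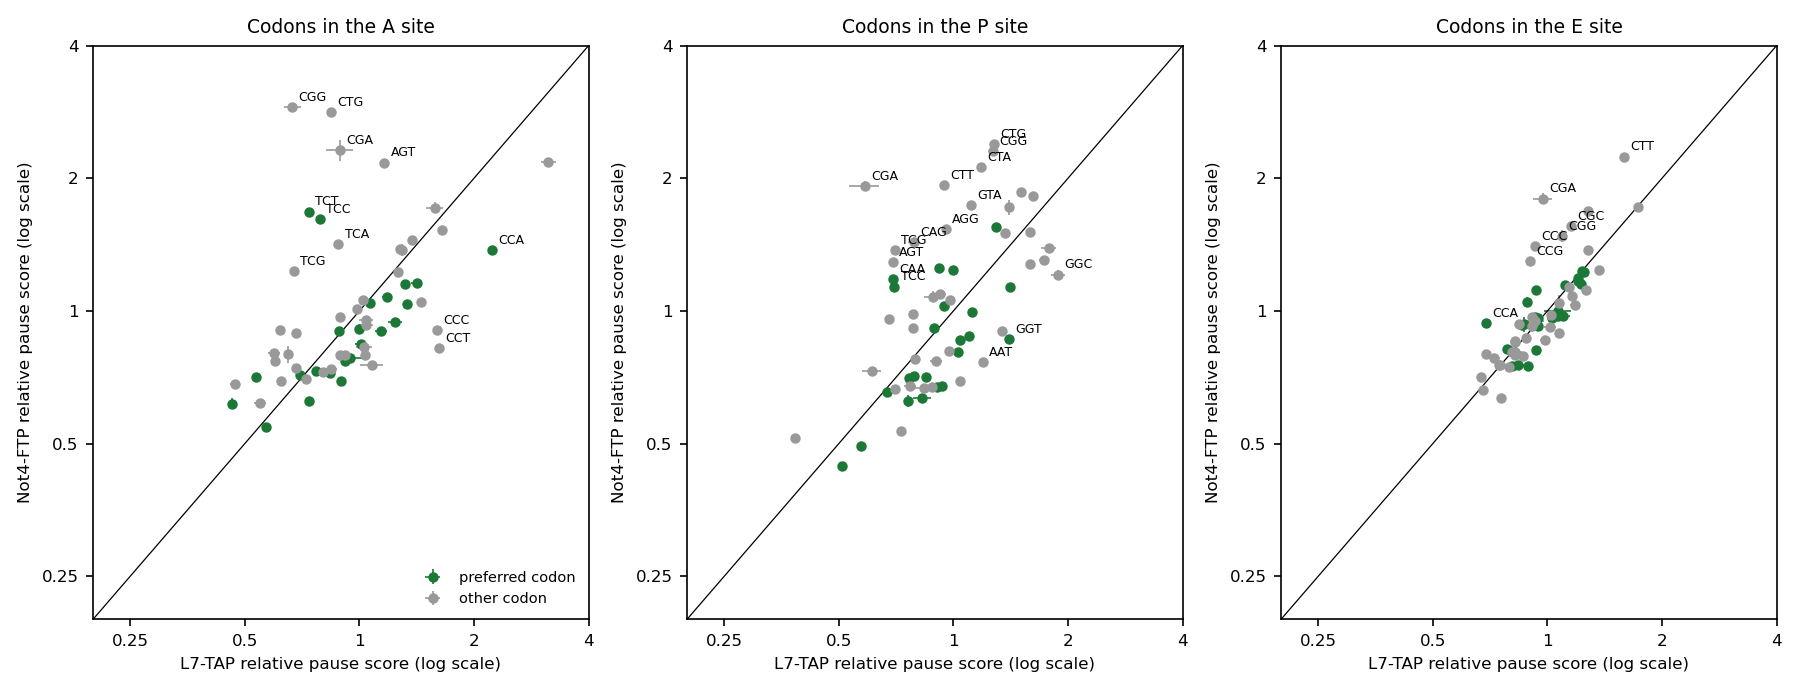
Relative pause score of each sense codon (1 = mean of all sense codons) in L7-TAP and Not4-FTP libraries for codons in the A, P and E sites; points are means of 2 libraries, bars the SD, and both axes are logarithmic. In the A site CGG (0.667 against 2.90) and CTG (0.845 against 2.82) lie farthest above the diagonal.

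**Figure D2:**
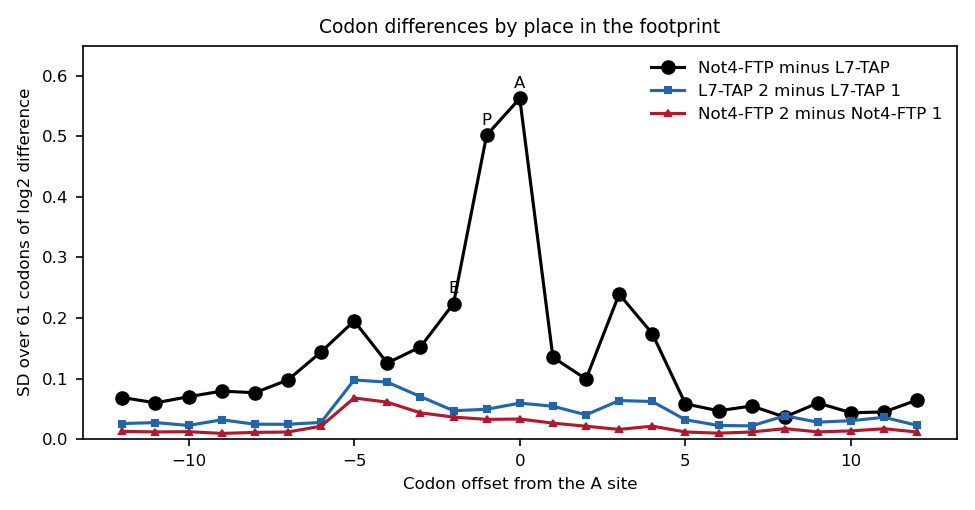
SD over 61 codons of the log2 difference in relative pause score, by codon offset from the A site, between groups and between replicates. The difference between groups reaches 0.563 at the A site and 0.502 at the P site.

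The series title names codon optimality, so the 23 codons that highly expressed yeast genes prefer were set against the 38 others. In the A site 16 of the preferred codons fell and 4 rose, whereas 14 of the other codons fell and 21 rose. TCT and TCC, preferred serine codons, were exceptions that rose strongly, and the preferred proline codon CCA had the largest decrease of the preferred group. In the P site 15 preferred codons fell and 6 rose, against 15 and 22 of the others.

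The mean log2 score of preferred minus other codons went from −0.03 to −0.25 in the A site, a difference of −0.21, and from −0.16 to −0.44 in the P site, a difference of −0.27, with both Not4 libraries below both L7 libraries. The mean change of the preferred codons was −0.05 in the A site and −0.09 in the P site, and that of the other codons 0.16 and 0.19. The exact two-sided permutation test gave p = 0.333 at each site, the smallest p that 2 against 2 libraries allow. The camera test gave adjusted p = 0.0945 in the A site, 0.146 in the P site and 0.662 in the E site. With camera the group of preferred codons was therefore not called. The fry test, which does not set a list against the other codons, gave adjusted p = 0.0211, 0.00200 and 0.331 in these sites. For the next test, codons that were not called were counted with the lowered ones, as not raised. Fisher's exact test of raised or not against preferred or other gave p = 0.00654 in the A site and 0.0191 in the P site. It gave 0.417 in the E site, and it treats codons as independent, which they are not. Across the 61 codons, which are not independent replicates, the P-site change was lower for codons that ribosomal protein genes use more often than other genes. Pearson's r was −0.42 (permutation p = 6.10e-04, adjusted p = 0.00549) and −0.43 without the 2 codons farthest from the median use. Spearman's rho was −0.38 (permutation p = 0.00273, adjusted p = 0.0164), in a family of 18 relations. With the other planned measure, use relative to synonymous codons, Pearson's r was −0.29 (permutation p = 0.0231, adjusted p = 0.0808) and Spearman's rho −0.33 (permutation p = 0.00932, adjusted p = 0.0419). The P-site score itself had r = −0.47 (permutation p = 7.00e-05, adjusted p = 0.00126) in Not4 ribosomes and −0.14 (permutation p = 0.291, adjusted p = 0.437) in L7 ribosomes. The A-site change had r = −0.27 (permutation p = 0.0353, adjusted p = 0.0907).

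The next comparison asked which mRNAs the Not4-bound ribosomes were translating. The kinase gene YAK1, which acts in the glucose response, held the largest excess: 64.9 ± 5.13 footprints per 1000000 (FPM; SD, n = 2) in L7 and 17158 ± 207 in Not4, a 263-fold difference that made it the gene with most footprints in both Not4 libraries (1.69% each). PUF2, PUF3 and JSN1, which encode RNA-binding proteins of the Pumilio family, were 112-fold, 52.3-fold and 44.0-fold higher, WHI4, an RNA-binding protein of cell size control, 75.0-fold, and the nuclear pore gene NUP100 60.03-fold. Genes of the Ty2 retrotransposon were also near the top. At the other end, GRE2, a methylglyoxal reductase gene, fell from 1374 ± 64.5 to 20.2 ± 1.26 FPM, and LYS9 of lysine synthesis fell from 1894 ± 29.1 to 60.8 ± 1.03.

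Of 3277 genes, 1562 had a higher and 1397 a lower share of footprints in Not4, and 318 did not pass. The difference exceeded 2-fold in 769 and 672 genes, and 8-fold in 139 and 23, of which 82 of the 139 belonged to 2 families of retrotransposon genes that share reads. The log2 changes were 8.04 for YAK1 (YJL141C, chromosome X, 147967 to 150390 in the R64 build, adjusted p = 2.34e-17), 6.80 for PUF2 (YPR042C, chromosome XVI, 650435 to 653662), 6.23 for WHI4 (YDL224C, chromosome IV, 54397 to 56346), 5.91 for NUP100 (YKL068W, chromosome XI, 310199 to 313078), 5.71 for PUF3 (YLL013C, chromosome XII, 122075 to 124714) and 5.46 for JSN1 (YJR091C, chromosome X, 595061 to 598336). The next 4, YOR192C-B, YOR343W-B, YDR210W-B and YBL100W-B, were near-identical Ty2 copies with changes from 5.28 to 5.33, and which copy was translated is uncertain. The decreases were led by GRE2 (YOL151W, −6.05), LYS9 (YNR050C, −4.95), CIS1 (YLR346C, −3.88) and RPS31 (YLR167W, −3.86), a fusion of ubiquitin and a ribosomal protein. Then came the peroxiredoxin gene AHP1 (YLR109W, −3.83), the citrate carrier gene CTP1 (YBR291C, −3.73), ENO2 of glycolysis (YHR174W, −3.60), the cyclophilin gene CPR1 (YDR155C, −3.57), YDR154C, an open reading frame that overlaps CPR1 (−3.65), and the arginase gene CAR1 (YPL111W, −3.57). Scaling by library totals moved the median change of all genes from 0.08 to 0.40, and scaling by the median of ratios moved it to 0.00. Changes are relative to TMM scaling, and 52.8% of the calls were higher, 62.6% with totals, and as many higher as lower (1479) with the median of ratios.

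**Figure D3:**
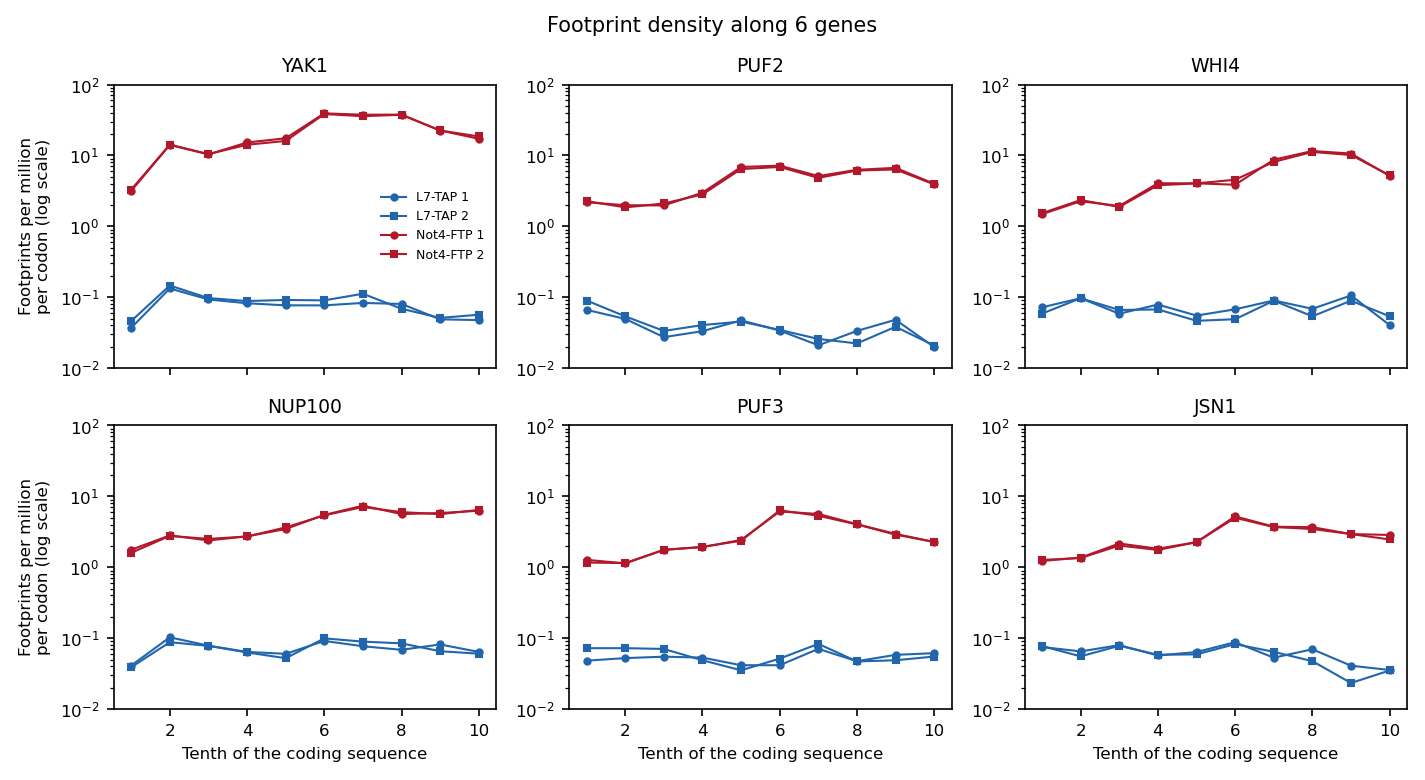
FPM per codon (logarithmic axis) in each of 10 equal parts of the coding sequence of 6 genes, 1 line per library. The Not4-FTP lines lie above the L7-TAP lines in every part, and in YAK1 the ratio goes from 77.6 in the first part to 503 at its highest.

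Among the genes of the Ccr4-Not complex itself, CDC39, the scaffold Not1, had 3.94-fold and the deadenylase gene CCR4 3.502-fold more footprints in the Not4 pulldown. NOT3 (log2 change 1.24), the deadenylase gene POP2 (0.84) and CAF40 (0.65) rose too. CDC36, the Not2 subunit, fell by 1.57. The tagged gene MOT2 itself moved little (0.17, adjusted p = 0.00525) and was not called with the median of ratios (0.09, adjusted p = 0.0931) or without Not4-FTP replicate 2 (0.15, adjusted p = 0.0699). NOT5 stood at −0.05 (adjusted p = 0.310), at 0.26 (adjusted p = 3.93e-04) with scaling by library totals and at −0.14 (adjusted p = 0.0181) with the median of ratios. Of 8 measured members 6 rose and 1 fell, and the list was not called (adjusted p = 0.175, or adjusted p = 0.384 with an estimated correlation). The list of tagged genes, MOT2 with RPL7A (−2.50) and RPL7B (−2.50), whose reads cannot be fully told apart, was not called either (adjusted p = 0.199), but it was without either Not4 library (adjusted p = 0.0307 and 0.0287).

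Of 137 ribosomal protein genes 134 fell, with a median log2 change of −2.27, among them RPS31, RPP2B (−3.44) and RPL36B (−3.17) (adjusted p = 0.268 with an estimated correlation). RPL4A (1.01) and RPL4B (1.13), near-identical copies named after their values were seen, rose together with RPS28B (0.23). Of 18 glycolysis genes 17 fell, with a median of −2.46, led by ENO2, ENO1 (−3.21) and the alcohol dehydrogenase gene ADH1 (−2.89) (adjusted p = 0.330 with an estimated correlation). HXK1, the hexokinase gene that glucose represses, rose (1.54) and was also named after its value was seen. Translation factors fell in 25 of 30 cases, with TEF1 and TEF2 (both −3.17), the copies that encode elongation factor 1A, in front and the initiation factor eIF4A gene TIF1 at −1.99 (adjusted p = 0.330 with an estimated correlation). In contrast, 51 of 53 mitochondrial ribosomal protein genes rose, with a median of 1.001, led by MRPL4 (2.41), MRPL3 (2.29) and MRPL7 (2.14) (adjusted p = 0.268 with an estimated correlation).

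Of 24 gene lists fixed in advance, 23 had measured genes and 15 were called with camera, 12 lower and 3 higher. Across 3140 genes the change fell with L7 footprints per codon (Spearman's rho −0.66), a level that enters the change itself. The list tests did not take that level into account. None of the 15 calls held with an estimated correlation, with which camera passed 1 list at unadjusted p under 0.05. That version has few residual degrees of freedom with 4 libraries, so it can lose calls whatever the correlation. For mitochondrial ribosomal proteins the estimated correlation was negative (−0.010), and camera with it still gave an unadjusted p of only 0.0231. With the preset correlation the adjusted p was 7.84e-27 for ribosomal proteins, 3.95e-06 for glycolysis, 1.45e-05 for translation factors and 1.73e-06 for mitochondrial ribosomal proteins. Adjusted over the list alone, each of the 23 lists had as many called genes as over all genes.

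Enzymes and chaperones made up most of the other lower lists. Aminoacyl-tRNA synthetase genes fell in 17 of 18 cases (median −0.98), among them GUS1 (−2.09), DPS1 (−1.95) and SES1 (−1.69), with adjusted p = 6.32e-05, and adjusted p = 0.362 with an estimated correlation. Chaperone genes fell in 21 of 26 (median −1.12), among them the ribosome-bound ZUO1 (−2.86) and the near-identical SSA2 (−2.51) and SSA1 (−2.44), with adjusted p = 5.61e-04, and adjusted p = 0.268 with an estimated correlation. Proteasome genes fell in 28 of 31 (median −0.78), with PRE9 at −1.66, RPT2 at −1.32 and RPT6 at −1.31, adjusted p = 8.78e-06, and adjusted p = 0.268 with an estimated correlation. Amino acid synthesis genes fell in 40 of 50 (median −0.79), with LYS9, LYS20 (−3.42) and LYS1 (−3.10) in front, adjusted p = 8.19e-06, and adjusted p = 0.376 with an estimated correlation. Ergosterol genes fell in 13 of 17 (median −1.26), with ERG10 at −2.02, ERG1 at −1.93 and ERG20 at −1.83, adjusted p = 0.00380, and adjusted p = 0.268 with an estimated correlation. The 10 measured histone genes all fell (median −1.14), HHO1 by 1.93, HTB1 by 1.74 and HTB2 by 1.34, with adjusted p = 8.84e-04, and adjusted p = 0.362 with an estimated correlation.

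Ribosome biogenesis genes fell in 32 of 40 cases (median −0.58), with NSR1 at −2.35, DBP2 at −1.86 and GAR1 at −1.81, adjusted p = 0.00206, and adjusted p = 0.330 with an estimated correlation. Genes of the tricarboxylic acid cycle fell in 10 of 11 (median −1.14), with IDH1 at −1.76, KGD2 at −1.38 and CIT1 at −1.35, adjusted p = 0.00206, and adjusted p = 0.268 with an estimated correlation. Nuclear genes of the respiratory chain fell in 24 of 34 (median −0.54), with ATP3 at −1.54 and ATP2 at −1.07, while SDH1 rose by 1.58, adjusted p = 0.00780, and adjusted p = 0.268 with an estimated correlation. Without either Not4 library that list was not called (adjusted p = 0.122 and 0.121). The higher lists, besides mitochondrial ribosomal proteins, were cell cycle genes, with 11 of 13 raised, and the SAGA and TFIID coactivators, with 14 of 19. The cyclin genes CLB1 (3.56), CLN2 (2.56) and CLB2 (2.16) led the cell cycle list (median 0.98, adjusted p = 0.0307, and adjusted p = 0.362 with an estimated correlation), which was not called with library totals (adjusted p = 0.0579) or without either Not4 library (adjusted p = 0.0700 and 0.0706). SGF29 (2.06), UBP8 (1.52) and TAF12 (1.19) led the coactivators (median 0.84, adjusted p = 0.0419, and adjusted p = 0.470 with an estimated correlation). They were not called with capped positions (adjusted p = 0.0540), without L7-TAP replicate 2 (adjusted p = 0.0534) or without either Not4 library (adjusted p = 0.326 and 0.340).

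Lists that were not called had members on both sides. Genes of mRNA decay were split, with 15 higher, 10 lower and 3 not called (median 0.17, adjusted p = 0.492), and so were stress and trehalose genes, with 10 higher and 8 lower (median 0.29, adjusted p = 0.781). RNA polymerase II genes had 5 higher and 5 lower of 12 (median −0.09, adjusted p = 0.781), and secreted cell wall genes 10 higher and 9 lower of 21 (median 0.07, adjusted p = 0.999). The medians of these last lists changed sign with the scaling, to 0.23 with library totals for RNA polymerase II and to −0.01 with the median of ratios for the cell wall. Only 8 of 21 genes of the secretory endoplasmic reticulum (median 0.44, adjusted p = 0.437) and 5 of 24 plasma membrane transporter genes (median 1.15, adjusted p = 0.231) were measured in all 4 libraries. The list of mitochondrially encoded genes was not analysed here.

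**Figure D4:**
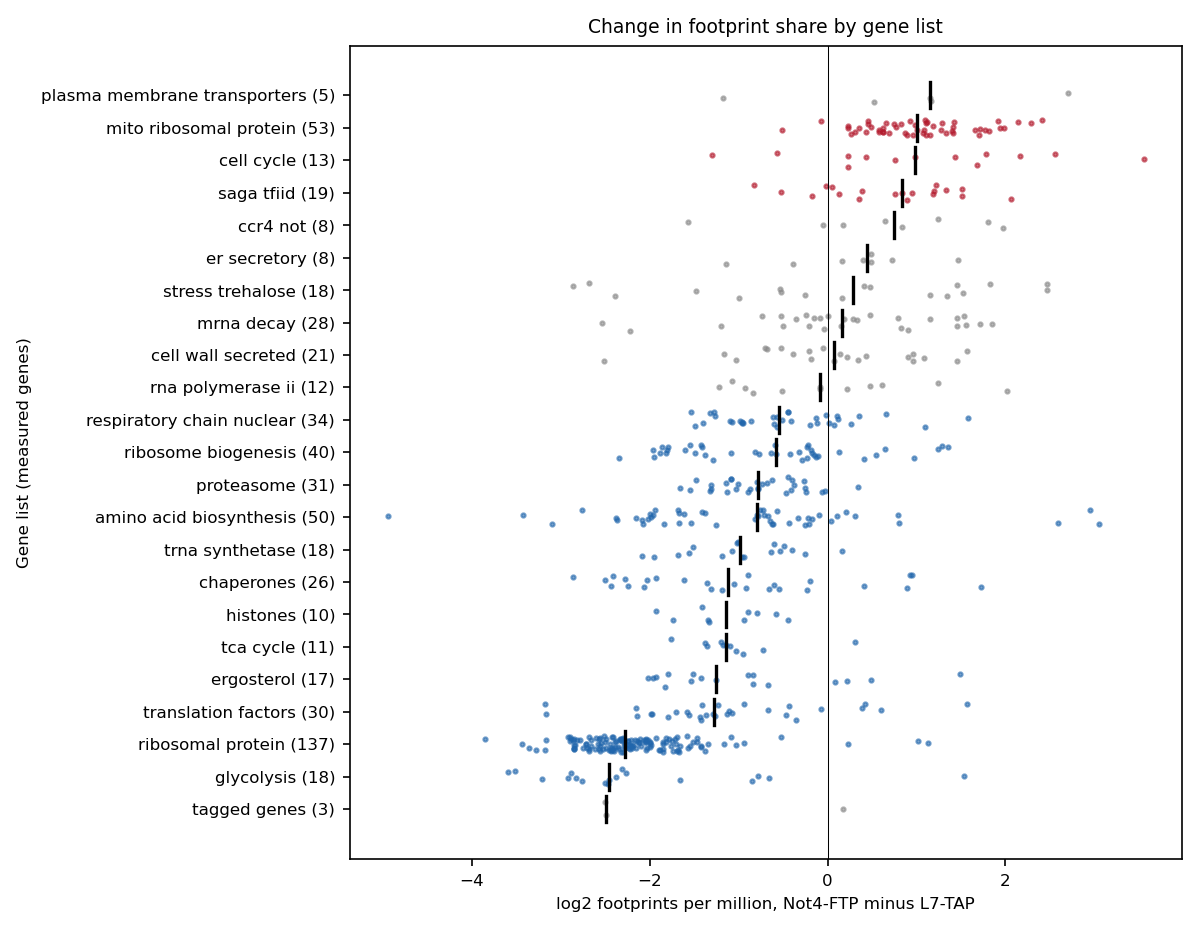
Log2 change in FPM (Not4-FTP minus L7-TAP) of each measured gene, by gene list; black bars are medians, blue and red lists were called lower and higher with camera at its preset correlation and lost the call with an estimated one, grey lists were not called, and the cell wall and RNA polymerase II medians change sign with the scaling. Ribosomal protein genes have a median of −2.27 and mitochondrial ribosomal protein genes one of 1.001. The test with an estimated correlation has few residual degrees of freedom with 4 libraries.

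Whether the pulldowns held ribosomes at different stages was asked with windows along the coding sequence. Not4 ribosomes were denser at the start: in 2997 genes of at least 120 codons the mean pause score of the first 20 codons rose from 0.582 ± 0.00247 (SD, n = 2) to 0.759 ± 0.000697. Over the start codon itself the mean score was 2.24 in L7 and 4.90 in Not4. The last 20 codons rose from 1.13 ± 0.0163 to 1.25 ± 0.00699. L7 ribosomes had a peak of 1.36 with codon 16 in the P site, where Not4 ribosomes had 0.710.

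The log2 change was 0.38 for the first 20 codons (adjusted p = 1.85e-05), 0.14 for the last 20 (adjusted p = 0.00421), −0.02 for the rest of the gene (adjusted p = 0.00536) and −0.01 for codons 21 to 50 (adjusted p = 0.623). The exact permutation test cannot give less than 0.333 here and gave 0.333 for the first 20 codons, the last 20 and the rest. With scores capped at 10, the change was 0.03 (adjusted p = 0.0221) over codons 21 to 50 and 0.000925 (adjusted p = 0.903) over the rest of the gene, and over codons 21 to 50 it was −0.03 (adjusted p = 0.00537) without L7-TAP replicate 1 and 0.0119 (adjusted p = 0.0936) without replicate 2. The change over the rest of the gene also lost its call without either Not4 library (adjusted p = 0.170 and 0.187).

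Strong pauses were defined as a score of at least 10 in both libraries of a group. They mark positions with many footprints for their gene, whether ribosomes stay there longer or are pulled down more often. In Not4 ribosomes the leucine codon CTG lay in the A site of 717 of these positions, 12.6% of those with a sense codon there, against 0.968% of all positions with one. CGG and CGA were 13.2-fold and 9.09-fold more frequent there than among all positions. In L7 ribosomes the proline codons CCG (8.59-fold) and CCA (3.85-fold) were enriched, and CTG lay at 44 positions. CCG was enriched in Not4 ribosomes as well (5.77-fold, 166 positions), and CCA stood at 1.17-fold there.

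There were 6676 strong positions in L7 and 6150 in Not4, and 1632 were shared. If positions were independent and equally likely, 29.8 would fall together. They are not, since near-identical copies that share reads count separately, so 29.8 is only a rough guide. The start codon held 5.76% of the strong positions in Not4 and 1.03% in L7, and the stop codon 7.25% and 3.74%. The counts and their order depend on the threshold and the coverage. At a score of 20 they were 1351 and 1521, and with at least 10 footprints at the position 5935 and 6147.

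Single positions were also compared one by one. By the planned test the largest increases were in BDP1, a factor of RNA polymerase III, with codon 572 in the P site, in the acetyltransferase gene GCN5 with codon 16, in CHS1 with codon 7, in RCF3 with codon 42, a pair of CTG codons, and in PXR1 with codon 10 and CGG in the A site. The largest decreases were in IOC2 with codon 343 and CCG in the A site, BUD4 with codon 1447, IKI1 with codon 303 and CCA in the A site, HIS3 with codon 152 and PFK1 with codon 755. Among positions with at least 10 footprints in every library, a limit chosen after the data were seen, the largest increases included RPL19A with codon 183, GET3 with codon 52 (CTA in the P site and CTG in the A site, log2 change 4.90) and the proteasome gene RPT3 with codon 60, again a pair of CTG codons (4.48).

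The planned test called 110519 of 1120027 positions higher and 21527 lower. However, 90.9% of the higher ones had no footprint in an L7 library, and 35.1% of the lower ones had none in a Not4 library. On simulated data it called 50008 unchanged positions. Leaving out either L7 library, limma called 0 positions, with 235651 higher and 123213 lower at unadjusted p under 0.05 when it was replicate 1. With at least 10 footprints in every library, 17583 of 93317 positions were higher and 26854 lower. Simulated data gave 13 false calls, but they held counting error only, and the real replicates varied by more. How many of the called positions are false is therefore not known. Among the higher positions of that test TCT lay in the A site 2.88-fold more often than among all tested ones and CTG 2.23-fold. Among the lower ones CCG was 2.02-fold and CCT 1.97-fold more frequent.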

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

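Of the tests below, the one on membrane proteins was chosen after the result was seen, and the one on depth before it.

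Signal outside the 4-library comparison: 1732 genes were listed in both Not4 libraries and in neither L7 library, against 6 the other way round. IRC9 (chromosome X, 147819 to 148211) had 46531 and 47920 footprints in Not4, but its reading frame overlaps the end of YAK1, whose last 10% held 44022 and 46073, so they cannot be told apart from those of YAK1. RPI1, a transcription factor gene, was 50.3-fold higher than a gene with 0.5 footprints per codon in L7 would be. Also among them were the sugar transporter genes HXT6 and HXT7, which are near-identical copies, the amino acid permease gene GAP1 (9.48-fold on the same scale), the phosphate transporter gene PHO84 (6.85-fold) and the translocon gene SEC61 (4.43-fold).

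The Not4 libraries were deeper, and depth as the cause for most of these genes was tested by scaling the Not4 libraries to the size of the shallower L7 library over the shared genes: 68.6% of the 1732 (1188 genes) still had 0.5 footprints per codon, which argues against it. A loss of membrane-bound ribosomes from the L7 pulldown may have a part. Of the genes of the endoplasmic reticulum and plasma membrane lists that had 0.5 footprints per codon in the scaled Not4 libraries, 36.1% (13 of 36) were listed in both L7 libraries, against 70.9% of other genes (Fisher's exact test, p = 2.05e-05, adjusted p = 1.03e-04 over 5 tests). The plasma membrane list passed alone (5 of 19, adjusted p = 2.01e-04) and the endoplasmic reticulum list did not (8 of 17, adjusted p = 0.0709). Secreted cell wall genes, also made on membranes, went the other way: 21 of 21 were listed, against 70.5% of other genes (Fisher's exact test, adjusted p = 0.00182). The 3 lists together did not pass (34 of 57, 59.6% against 70.8%, adjusted p = 0.0784). A loss of membrane-bound ribosomes therefore stays open, as does a biological difference between ribosomes bound by Ccr4-Not and ribosomes in general. The minimum that the authors applied per gene was not stated, and 0.5 was read from the lowest listed values, with 1 gene in L7-TAP replicate 2 below it (0.463), so the folds are not strict lower bounds.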

How the results depend on the processing

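The codon, gene and list results kept direction and threshold under most alternatives, and where they did not the cause was not tested unless given. Among named items, 1068 gene, 747 codon and 330 gene list values kept both their direction and their side of the threshold. The direction turned in 1, 9 and 4 values, and the others kept it but crossed the threshold. The added alternatives were chosen after seeing the data. The exact permutation test called 0 codons at each site by construction, since its smallest p is 0.333. Moving the site by 1 codon left 17 lowered codons in the A site (3′) and 22 changed codons in the E site (5′, 11 raised and 11 lowered). Leaving out 1 library gave 12 (without Not4-FTP replicate 1) to 22 lowered codons in the E site.

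Codon lists called in the A site (4) numbered 2 with the stricter filter, 2 weighted by footprints, 0 moved 5′, 2 moved 3′, 13 with fry and 0 with an estimated correlation. In the P site (0) they numbered 1 without gene ends, 1 capped, 1 moved 5′, 4 moved 3′, 1 with the 50% of genes least changed, 14 with fry, and 0 to 2 leaving out 1 library (2 without L7-TAP replicate 1). In the E site (1) they numbered 2 weighted, 0 moved 3′, 3 with the replicate block, 2 with the 50% least changed, 9 with fry, 0 with an estimated correlation, and 1 to 3 leaving out 1 library (3 without either L7 library). With an estimated correlation 0 gene lists were called, and with fry 22. These signs turned: CGT in the A site weighted (−0.22); AGG in the A site without ends (−0.0178), capped (−0.000645), with 1 gene per family (−0.0394) and with the 50% least changed (−0.0884); CAT in the E site weighted (0.32). CGT at the E site turned without Not4-FTP replicate 2 (0.00692; −0.0329 without replicate 1) and with the 50% least changed (0.00633), and AGG there with the stricter filter (−6.1e-05). RNA polymerase II (0.23) and NOT5 (0.26) turned with library totals, cell wall genes without ends (−0.0321) and with the median of ratios (−0.0130), and stress genes without ends (−0.00527).

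The 30 codons after the first window gave −0.0543 with windows of 10, where they are codons 11 to 40 and not 21 to 50; codons 21 to 50 gave 0.0116 with the stricter filter, 0.0298 capped, and −0.0323 to 0.0119 leaving out 1 library; the rest of the gene gave 0.000925 capped and −0.0220 to −0.0201 leaving out 1 library. Strong positions in L7, Not4 and both numbered 26544, 24560 and 7924 at threshold 5, 1351, 1521 and 320 at 20, and 1940, 1778 and 462 with the stricter filter; with 1 L7 library they numbered 10617 to 11470. Higher single positions numbered 167211 with pseudocount 0.1, 13805 above 0 in all libraries, 17583 with at least 10 footprints, and 0 to 203509 leaving out 1 library. The lower ones numbered 0 to 5904, and with the replicate block limma called 0 and 0, with 223841 and 72923 at unadjusted p under 0.05. The 0 counts arose when either L7 library was left out; a lone library was assumed to vary like the other group. The block called 1559 and 1392 genes, and it pairs libraries by replicate number alone. Same-number differences had r = 0.11 across genes and 0.48, 0.41 and 0.40 across A, P and E codons. Something shared by libraries of the same number is therefore not excluded for the codons, and the main codon fits had no term for it. Not run were the DESeq2 and edgeR alternatives, since recovered footprints were fitted with limma, and tRNA gene numbers; a mean over listed positions changes nothing, since all positions are listed.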

Other observations

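Everything in this part was chosen after the results were seen, except the test of glutamine and asparagine content, which was set before its result.

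The Ty1 retrotransposon carries a programmed frameshift, at which ribosomes slip by 1 base on the codon CTT while the rare arginine codon AGG waits in the A site. In 32 annotated copies of its first reading frame the median pause score with CTT in the P site and AGG in the A site was 10.97 in L7 and 47.6 in Not4, and 1 codon later, with AGG in the P site, it was 32.2 and 92.8. Scores were higher in Not4 in 32 of 32 copies at both places, but the copies share reads and are not independent. In 10 copies from the Ty2 family the median score with CTT in the P site was 1.30 in L7 and 1.10 in Not4, with 0 of 10 higher in Not4. With AGG in the P site the L7 libraries disagreed, with scores from 1.25 to 2.05 in replicate 1 and from 0.226 to 0.350 in replicate 2, and the Not4 scores lay between, from 0.550 to 1.01. Shares were taken of the footprints in genes listed in all 4 libraries, counted at each copy. The family with Ty1 took 0.712% and 0.720% of them in L7 and 23.8% and 24.3% in Not4. Its 62 genes had a median log2 change of 4.78. The 20 genes of the Ty2 family had one of 5.06.

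With CTG in both the P and the A site the mean score was 1.13 and 1.39 in the L7 libraries and 15.9 and 15.5 in the Not4 libraries, and the pair CAG-CTG had the largest log2 change of 3025 pairs (3.73). Across these pairs, which are not independent, the change of a pair correlated with the sum of its single-codon changes (r = 0.889). Other large gene increases outside families were those of SMY2 (4.56) and SYH1 (4.05), which encode GYF-domain proteins, the longevity gene ECL1 (4.55), the glucose repressor gene MIG1 (4.18) and MPT5 (3.78), another Pumilio family gene. The RNA polymerase II subunit genes RPO21 (2.02) and RPB2 (1.24), the largest subunits, rose while RPB5 (−1.22) and RPO26 (−1.08) fell. All 7 measured genes of lysine synthesis fell, with a median of −2.77 against −0.71 for the 43 other amino acid synthesis genes. In PMA1, the plasma membrane proton pump gene, 70.6% and 69.0% of L7 footprints but 48.0% and 48.5% of Not4 footprints lay in the first 20% of the coding sequence, and its total rose by 2.70 on the log2 scale.

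For the codon differences at the A and P sites, thinning all libraries to the shallowest left at least 0.9988 of their SD. Random thinning does not shift the mean score of a codon on average, so this test cannot decide about depth. The SD at both sites was at least 2.096 times that at any offset outside E, P and A, which argues against sequence bias at the footprint ends as the whole cause. With 1 gene per family, or with the 50% of genes least changed, the lowest share of the SD left was 0.9988, which argues against a few genes as the cause. A difference between the strains or their cultures cannot be told apart from the pulldown, since 0 strains had libraries of both pulldowns. What Ccr4-Not binds therefore stays open beside it.

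For YAK1, PUF2, WHI4, NUP100, PUF3 and JSN1, capping each position at 10 times the gene mean left log2 changes of at least 5.52, which argues against single pile-ups. At most 1.22% of their 10-codon windows occur in another gene, which argues against reads shared with near-identical genes. Windows were compared in the frame of each gene, so overlapping reading frames, such as IRC9 on YAK1, were not covered. From the upstream 50% to the downstream 50% of these genes the Not4 to L7 ratio rose by at least 0.98 on the log2 scale, beyond the largest replicate difference (0.374), so more mRNA or more initiation in the Not4 strain is unlikely to be the cause of that rise, though some other genes rose as much (median of all genes 0.01, with −0.99 and 1.25 as the 2.5 and 97.5 percentiles, the 6 genes from percentile 96.1 to 98.8). The excess over the upstream 50%, at least 4.71, cannot be told apart from a difference in mRNA level, which was not measured. A candidate explanation, as a hypothesis, is that Not4 holds ribosomes whose nascent chains are rich in glutamine and asparagine: across 3140 genes the change rose with that content (Spearman's rho 0.361, permutation p = 1e-04, the smallest 10000 permutations can give), with rho 0.267 given the share of preferred codons and 0.211 given also length and L7 level, and all 6 genes lay above the 90th percentile of content. Genes are not independent replicates, and the change also fell with the share of preferred codons (rho −0.48) and with the L7 level (rho −0.66), which enters the change itself, so the test does not single out this explanation.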
